A study of Homo sapiens with 6 samples.

How the data were processed

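Gene expression was measured by RNA sequencing in HTR-8/SVneo cells, an immortalised line made from human extravillous trophoblast, the invasive cell of the placenta. The 6 libraries were 3 untreated controls and 3 from cells given growth differentiation factor 11 (GDF-11) at 30 ng/mL for 3 hours. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with an Illumina stranded mRNA kit. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical.

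The deposited table held expected counts, that is, estimated read counts per Ensembl gene given to 2 decimals and not scaled to depth. Per the submitters' processing notes, HISAT2, StringTie, RSEM and DESeq2 were used with the GRCh38 (hg38) genome, without versions or roles. The annotation release and the strand setting of the counting are not given in the sources used here. The table had 63249 rows, of which 8 named no gene and held no counts, so their share of the counts was nil and they were left out. Of the 63241 genes, 42640 had a symbol and 31053 had a count in at least 1 library. The authors' 2 mean columns equalled the row means of the 3 libraries of a group and were not tested. Expected counts were rounded to whole numbers before any count test. Genes whose deposited values were not whole in any library had reads divided between genes by the authors' counting, and they are named as such where they appear. Reads from overlapping genes on opposite strands are uncertain for the same reason, since the strand setting is not given.

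Library totals ranged from 16741529 to 21183898 rounded counts. Genes with too few counts were removed with filterByExpr, which left 15920, and libraries were scaled with TMM. The comparison of GDF-11 with control used edgeR's quasi-likelihood test on all 6 libraries with group as the only term, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Normalised counts (CPM) are counts scaled to the TMM-adjusted library sizes with edgeR's cpm function, given as mean ± SD. Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The counting intervals are exact binomial at 95%, the floor for a group without counts is 3 counts over the group, and both cover counting error alone. With 3 libraries against 3, an exact two-sided permutation test of 1 gene has 20 arrangements and cannot go below p = 0.1.

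The 27 gene lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named the 15 genes with the largest positive and the 15 with the largest negative log2 fold change among called genes with a symbol, a mean of at least 1 CPM and no overlap of the groups. It also named ANGPTL4 and GDF11 and up to 4 members per list with the smallest adjusted p and a mean of at least 1 CPM. Genes named outside it were chosen after their values were seen, except that any member of a fixed list could be given to show what moved. Lists were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 27 lists. Camera with a correlation estimated per list and fry were run beside it. Gene Ontology (GO) and KEGG terms written in the deposited table were tested with a one-sided hypergeometric test, with the tested genes that had any term of that kind as background and terms of 10 to 500 genes. Up to 6 terms per direction were named by smallest p, and a term sharing more than 50% of its called genes with a named term was skipped. Gene positions, types and exonic lengths came from GENCODE v29 on GRCh38, matched by Ensembl identifier, which covered 15293 of the tested genes (96.1%). The table's own gene type column was not used, because 441 genes it calls nonsense-mediated decay are protein-coding in GENCODE v29.

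Replicates of a group were compared with a chi-square per degree of freedom over genes with a summed count above 20. It lay between 1.89 and 10.9 for the 6 pairs, so no pair was as close as sampling noise alone (about 1) would make a library deposited again. The procedure was tested on simulated counts for 15688 genes drawn from the means and depths of this comparison. At each size of change, 48 or 49 changed genes were tested. It recovered 62.5% of genes changed by 0.5 on the log2 scale and 85.7% of those changed by 1. It also recovered 97.9% of those changed by 2 and all of those changed by 3. Of 182 calls, 14 (7.7%) were unchanged genes. Far fewer genes were changed there than the 3471 called in the data. The adjusted p depends on that share, so recovery in the data may differ.

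The alternatives were median-ratio size factors, library totals without a scaling factor, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2, limma-voom, a robust quasi-likelihood fit, the replicate number as a block, and leaving out each library in turn. Offsets that remove each library's trend with exonic gene length were added after seeing the data.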

Results

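RNA was sequenced from HTR-8/SVneo cells, a line made from human extravillous trophoblast. Cells were sampled after 3 hours with 30 ng/mL GDF-11 (3 libraries) or without treatment (3 libraries). GDF-11 is a secreted ligand of the TGF-β family that signals through activin receptors and the transcription factors SMAD2 and SMAD3. The control libraries held 18838912, 19234384 and 17842411 rounded counts, and the GDF-11 libraries held 16741529, 21183898 and 17663913. Transcripts of the mitochondrial genome made up 5.84% to 6.14% of the counts in the controls and 5.50% to 5.69% in the GDF-11 libraries. The 10 most abundant genes took 5.89% to 6.4985% of any library. On the main axis of a principal component analysis, which held 53.7% of the variance, the controls lay between -29.5 and -26.5 and the GDF-11 libraries between 27.0 and 28.6.

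The comparison of GDF-11 with control asks which transcripts change within 3 hours of the ligand. ANGPTL4, SERPINE1, PMEPA1, NEDD9 and SOX4 were among the genes with the largest increases, and CITED2, RNF144B and IFIT2 among those with the largest decreases. SERPINE1, which encodes plasminogen activator inhibitor 1, rose from 19.7 ± 2.58 to 881 ± 35.1 CPM (SD, n = 3 per group), a 44.8-fold change (log2 fold change 5.48, SE 0.09, adjusted p = 5.65e-12 in edgeR's quasi-likelihood test). PMEPA1, which encodes a membrane protein that restrains SMAD signalling, rose from 10.7 ± 1.96 to 449 ± 3.88 CPM. NEDD9, a scaffold of focal adhesions, rose 20.2-fold to 97.1 ± 3.13 CPM, and the transcription factor gene SOX4 rose 15.7-fold from 22.95 ± 0.51 to 360.5 ± 1.92 CPM. DACT1, an inhibitor of WNT signalling, rose 15.9-fold, and FOSB, a subunit of the AP-1 transcription factor, rose 11.3-fold.

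Several of the 15 largest increases started from very few counts. ODAPH had 4 counts over the 3 controls against 252 over the GDF-11 libraries, a ratio of 65.9 (95% counting interval 25.4 to 244). FOXS1 had 3 against 128 counts, a ratio of 44.6 (14.9 to 219), and CYP24A1, which encodes the vitamin D 24-hydroxylase, had 3 against 118, a ratio of 41.1 (13.7 to 202). EGR2 rose from 7 to 125 counts, MGP, which encodes matrix Gla protein, from 14 to 237, and PLPP4 from 8 to 118. TNFSF15, a cytokine of the tumour necrosis factor family, rose 13.4-fold to 9.96 ± 0.76 CPM. TPM1-AS rose 12.5-fold, but it lies antisense to TPM1 and the deposited values of both genes were not whole in any library, so their reads were divided between genes.

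The decreases were smaller than the increases. CITED2, a transcriptional co-regulator, fell from 118 ± 0.59 to 27.2 ± 2.98 CPM (log2 fold change -2.12, SE 0.06, adjusted p = 8.11e-10 in edgeR's quasi-likelihood test). RNF144B, an E3 ubiquitin ligase gene, fell 4.92-fold from 10.8 ± 0.69 to 2.18 ± 0.38 CPM, and the interferon-induced gene IFIT2 fell 4.36-fold from 8.93 ± 0.73 to 2.06 ± 0.28 CPM. The receptor gene SSTR1 fell 3.62-fold, the receptor tyrosine kinase antagonist gene SPRY1 fell 3.73-fold, and SERPINB2, which encodes plasminogen activator inhibitor 2, fell 3.69-fold. PCDH18, CD200, TMCC3, TNFSF18, GPR37, OSGIN1 and B3GALT2 fell between 3.53-fold and 4.10-fold. IL24 (3.80-fold lower) and the pseudogene ENO1P1 (4.59-fold lower) had no whole deposited value in any library, so their levels are uncertain. PMEPA1, MGP, FOSB, IFIT2 and B3GALT2 also overlap genes on the opposite strand.

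**Figure D1:**
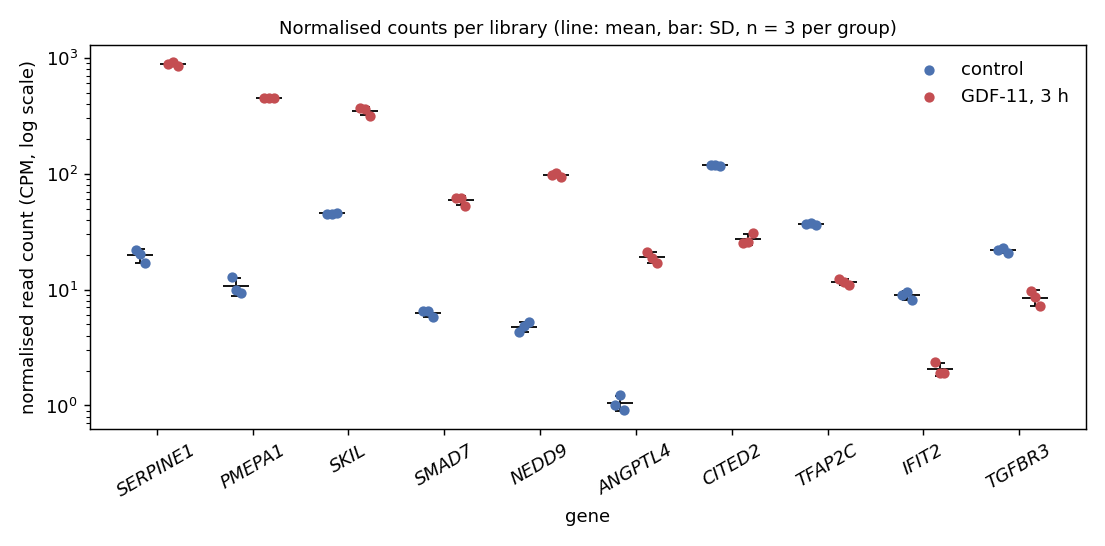
Normalised read counts (CPM, log scale) of 10 genes in each library, controls in blue and GDF-11 in red, with the mean as a line and the SD as a bar (n = 3 per group). SERPINE1 stands at 881 CPM with GDF-11 against 19.7 in controls, ANGPTL4 at 18.9 against 1.05, and CITED2 at 27.2 against 118.

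Of 15920 genes tested, 3471 (21.8%) were called, 2162 higher and 1309 lower with GDF-11. At 2-fold or more, 429 were higher and 122 lower. The groups did not overlap in 3460 of the called genes (99.7%), against 38.7% of all tested genes and 10% expected by chance for 3 against 3. The share among called genes largely follows from the call, which needs a difference beyond the spread within groups. Scaling by library totals called 1755 genes higher and 2282 lower, so that 43.5% of calls were higher against 62.3% in the main test, and DESeq2 called 749 lower. Without GDF-11 replicate 1, 2 or 3 the genes lower numbered 827, 811 and 785.

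**Figure D2:**
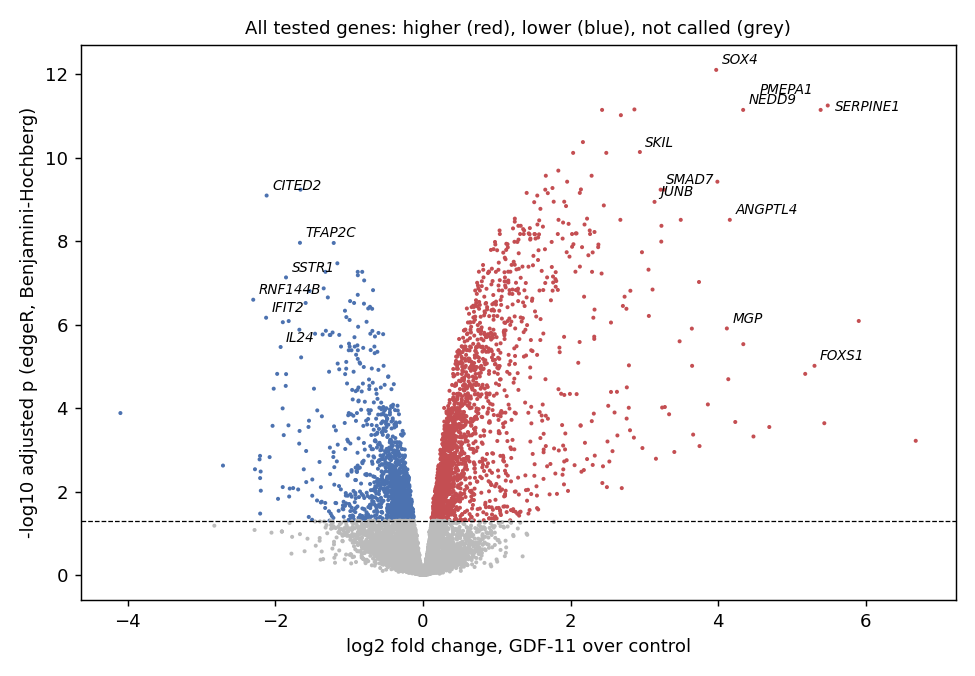
Log2 fold change of GDF-11 over control (x axis) against the -log10 adjusted p of edgeR's quasi-likelihood test (y axis) for 15920 genes, with genes called higher in red, lower in blue and neither in grey, and a dashed line at an adjusted p of 0.05. The 2162 higher genes reach further from 0 than the 1309 lower genes.

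ANGPTL4, which the series title names together with trophoblast invasion, encodes a secreted angiopoietin-like protein that inhibits lipoprotein lipase. The gene lies on the forward strand of chromosome 19 (GRCh38, 8363289 to 8374373). It rose 17.9-fold with GDF-11, from 1.05 ± 0.16 to 18.9 ± 2.09 CPM (n = 3 per group). The libraries held 17 to 24 counts in controls and 293 to 389 with GDF-11. Its log2 fold change was 4.16 (SE 0.15, adjusted p = 3.1e-09 in edgeR's quasi-likelihood test), and an exact two-sided permutation test of the CPM gave p = 0.1, the smallest that 20 arrangements allow. ANGPTL4 overlaps RAB11B-AS1 on the opposite strand, and 5 of its 6 deposited values were whole. GDF11 itself was at 30.9 ± 0.84 CPM in controls and 28.0 ± 0.73 with the ligand (adjusted p = 0.119 in edgeR), while scaling by library totals called it lower (log2 fold change -0.20, adjusted p = 0.0397, with a range of 0.0397 to 0.438 over the alternatives). GDF11 overlaps SARNP and had no whole deposited value.

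All 32 early target genes of TGF-β and activin (SMAD2/3) rose, with a median log2 fold change of 1.97. Besides SERPINE1, PMEPA1, NEDD9 and ANGPTL4 they included SKIL, a repressor of SMAD signalling (45.4 ± 0.57 to 348 ± 29.6 CPM, 7.67-fold), the inhibitory SMAD gene SMAD7 (log2 fold change 3.22) and the AP-1 subunit gene JUNB (8.80-fold). The count was also 32 adjusted over the list alone, and camera gave an adjusted p of 1.14e-34 (adjusted p = 0.0542 with an estimated correlation). Of 13 BMP (SMAD1/5) target genes, 10 rose and 0 fell, or 11 and 0 adjusted over the list alone (camera adjusted p = 1.39e-06, and adjusted p = 0.164 with an estimated correlation). ID1, ID2 and the inhibitory SMAD gene SMAD6 rose 1.91-fold, 2.80-fold and 2.60-fold, and the BMP antagonist gene GREM1 rose from 429 ± 23.9 to 1257 ± 22.6 CPM. No member of that list fell at an unadjusted p below 0.05 in edgeR or by DESeq2.

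Among 22 genes of the GDF-11 ligand, receptor, SMAD and antagonist list, 9 rose and 2 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.00057, and adjusted p = 0.18 with an estimated correlation). The activin and GDF-11 antagonist gene FSTL3 rose 4.36-fold from 19.3 ± 1.41 to 84.0 ± 3.03 CPM. The type II receptor gene BMPR2 rose 2.30-fold, TGFB1 rose 2.11-fold, and FURIN, which encodes a protease that processes TGF-β family ligands, rose 2.06-fold. The co-receptor gene TGFBR3 (log2 fold change -1.36) and SMAD2 (-0.24) fell. The activin receptor genes ACVR2A, ACVR2B and ACVR1B had log2 fold changes of 0.13, 0.15 and 0.09 and adjusted p of 0.273, 0.246 and 0.295 in edgeR.

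Invasion-related lists held members that moved both ways. Of 33 proteases and inhibitors, 11 rose and 4 fell, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.00237, and adjusted p = 0.18 with an estimated correlation). The largest increase was that of the inhibitor gene SERPINE1 (log2 fold change 5.48), which is also in the SMAD2/3 list. The median of the list was 0.12 and its mean 0.39. MMP2, which encodes gelatinase A, rose 4.80-fold from 9.59 ± 0.99 to 46.05 ± 3.62 CPM, ADAM19 rose 2.95-fold, and the inhibitor gene SERPINE2 rose 1.86-fold. The inhibitor genes TIMP1, TIMP2 and TIMP3 also rose (1.15-fold, 1.53-fold and 2.40-fold). The 4 that fell were the protease genes MMP1 (353 to 274 CPM), MMP16 (71.9 to 53.05 CPM) and ADAMTS1 (30.9 to 20.6 CPM) and the inhibitor gene SERPINB2, so both kinds moved in both directions. MMP9 (1.57 CPM in controls and 1.92 with GDF-11, adjusted p = 0.443), MMP14 (113 and 118 CPM, adjusted p = 0.445) and PLAU (178 and 162 CPM, adjusted p = 0.121) did not pass edgeR's test.

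Of 27 genes of epithelial-mesenchymal transition and adhesion, 17 rose and 2 fell, or 17 and 3 adjusted over the list alone (camera adjusted p = 6.94e-06, and adjusted p = 0.184 with an estimated correlation). The transcriptional repressor gene SNAI1 rose 9.38-fold from 1.58 ± 0.18 to 14.9 ± 1.42 CPM, fibronectin (FN1) rose 4.73-fold from 88.85 ± 13.95 to 420 ± 39.1 CPM, and the fibronectin receptor subunit gene ITGA5 rose 1.78-fold. TWIST1 (log2 fold change -0.41, adjusted p = 0.07) and TWIST2 (0.00, adjusted p = 0.999) did not pass the test, and CDH1 was below the count filter. Of 28 genes of the extracellular matrix and contractile cytoskeleton, 13 rose and 0 fell over all genes and adjusted over the list alone (camera adjusted p = 2.82e-07, and adjusted p = 0.18 with an estimated correlation). No member fell at an unadjusted p below 0.05 in edgeR or by DESeq2. Thrombospondin 1 (THBS1) rose 4.56-fold to 834 ± 15.4 CPM, the collagen IV gene COL4A1 rose 2.59-fold to 493 ± 27.0 CPM, and the cross-linking enzyme gene LOX rose 2.14-fold.

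**Figure D3:**
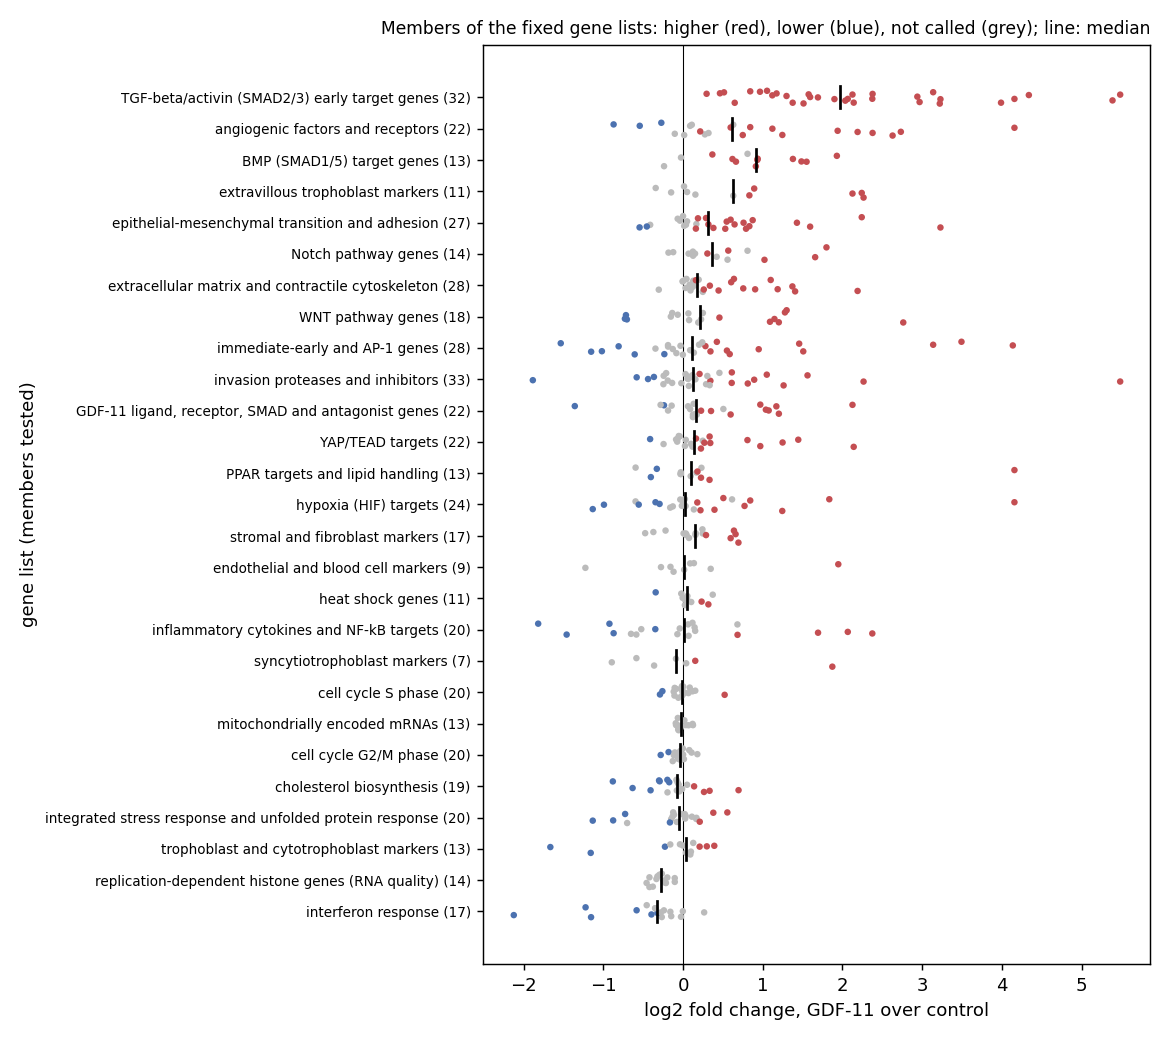
Log2 fold change of GDF-11 over control (x axis) for each tested member of the 27 fixed lists (rows, with the number tested), called higher in red, lower in blue and neither in grey, with the list median as a black line. All 32 SMAD2/3 target genes lie above 0, with a median of 1.97, and the interferon list has a median of -0.32.

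Of 22 angiogenic factors and receptors, 12 rose and 3 fell, or 14 and 3 adjusted over the list alone (camera adjusted p = 5.5e-07, and adjusted p = 0.164 with an estimated correlation). ANGPTL4 is a member and has the largest increase of the list. The members ANGPTL4, VEGFA and PDGFB, which all rose, are also in the SMAD2/3 target list, so the 2 lists are not independent. The growth factor gene PDGFA rose 3.83-fold to 64.0 ± 3.27 CPM and FGF2 rose 2.37-fold to 339 ± 5.2 CPM, although FGF2 shared reads with another gene in every library. Of 13 genes of PPAR targets and lipid handling, which include ANGPTL4, 4 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.402). CPT1A, which encodes an enzyme of mitochondrial fatty acid uptake, rose 1.26-fold, while LPIN1 and the lipid droplet gene PLIN2 fell 1.32-fold and 1.26-fold. Of 24 hypoxia (HIF) targets, which also include ANGPTL4, 9 rose and 5 fell, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.17). The glycolytic regulator gene PFKFB3 rose 3.57-fold and the glucose transporter gene SLC2A1 rose 1.71-fold, DDIT4 fell 2.19-fold, and PGK1 was at 529 CPM in controls and 530 with GDF-11 (adjusted p = 0.982).

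Immediate-early and AP-1 genes moved in both directions, with 11 of 28 higher and 6 lower, or 13 and 7 adjusted over the list alone (camera adjusted p = 0.0981). MYC rose 2.84-fold to 226 ± 6.86 CPM, while FOS (log2 fold change -0.08, adjusted p = 0.78), JUN (0.09, adjusted p = 0.265) and EGR1 (-0.35, adjusted p = 0.134) did not pass the test. Among 20 inflammatory cytokines and NF-κB targets, 4 rose and 5 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.628). The interleukin-6 family genes IL11 and LIF rose 5.18-fold and 4.19-fold, and IL1B and BIRC3 fell 3.52-fold and 2.75-fold. This list had a median of 0.01 and a mean of 0.04, while camera ranked it lower. Of 17 interferon response genes, 0 rose and 6 fell, or 0 and 7 adjusted over the list alone (camera adjusted p = 1.39e-05, and adjusted p = 0.18 with an estimated correlation), and none rose at an unadjusted p below 0.05 in edgeR or by DESeq2. IFIT3 and IFIT1 fell 2.33-fold and 2.23-fold, whereas STAT1, a mediator of interferon signalling, was at 109 CPM in controls and 107 with GDF-11 (adjusted p = 0.798).

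Of 22 YAP/TEAD target genes, 10 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00346, and adjusted p = 0.321 with an estimated correlation). The call was lost without control replicate 3 (camera adjusted p = 0.051, with a range of 0.00113 to 0.051 over the libraries left out). CCN2, which is also a SMAD target, rose 4.41-fold to 198 ± 11.4 CPM, DLC1 rose 2.72-fold, and AMOTL2 had a log2 fold change of 0.02 (adjusted p = 0.805). Of 14 Notch pathway genes, 5 rose and 0 fell, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.00057, and adjusted p = 0.207 with an estimated correlation). No Notch pathway gene fell at an unadjusted p below 0.05 in edgeR or by DESeq2. The ligand gene JAG1 rose 3.48-fold, the glycosyltransferase gene LFNG 3.15-fold and the target gene HES1 2.03-fold. Of 18 WNT pathway genes, 7 rose and 3 fell, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0575). WNT7B and WNT5B rose 2.46-fold and 2.42-fold, and the WNT antagonist gene DKK1 fell 1.64-fold from 325 ± 12.2 to 198 ± 2.73 CPM.

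Of the 3 lists of trophoblast markers, camera called only the extravillous list. Of 11 tested extravillous trophoblast markers, 5 rose and 0 fell, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.000316, and adjusted p = 0.164 with an estimated correlation). No marker of this list fell at an unadjusted p below 0.05 in edgeR or by DESeq2. Those that rose over all genes were MMP2, FN1, FSTL3, ITGA5 and SERPINE2, and all of them are also in other lists. FSTL3 is in the SMAD2/3 and GDF-11 ligand lists, MMP2 and SERPINE2 in the protease list, and FN1 and ITGA5 in the epithelial-mesenchymal list. HLA-G, the surface marker of this cell type, was below the count filter, and ASCL2, PAPPA2, LAIR2, HTRA4, PRG2 and TAC3 were not tested either. Nor were KRT19, ELF5, TP63, CDX2 and CDH1 of the trophoblast and cytotrophoblast list. Among stromal markers, controls held COL1A1 at 592, VIM at 1245 and PDGFRB at 36.6 CPM. Among trophoblast markers they held KRT8 at 749 and KRT18 at 682 CPM. These levels do not settle whether the line is a pure extravillous population. The rises in the matrix, adhesion and extravillous lists are changes in this line and cannot be assigned to that cell type. Of 13 trophoblast and cytotrophoblast markers, 3 rose and 3 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.841). The transcription factor gene TFAP2C fell 3.17-fold from 36.7 ± 1.02 to 11.6 ± 0.71 CPM and TFAP2A fell 2.23-fold from 135 ± 9.99 to 60.5 ± 1.75 CPM, though TFAP2A shared reads with another gene in every library. TEAD4 rose 1.31-fold, and GATA3 was at 11.45 CPM in both groups (adjusted p = 0.992). The median of this list was 0.04, its mean -0.15, and camera ranked it lower.

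Of 7 tested syncytiotrophoblast markers, 2 rose and 0 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.971), with a median of -0.09, a mean of 0.02 and a higher rank in camera. The chorionic gonadotropin gene CGB7, a member of a multigene family, rose 3.66-fold to 3.56 ± 0.19 CPM, and SDC1 rose 1.11-fold (adjusted p = 0.0256), a call lost with library totals, with the replicate block, without control replicate 2 and without any GDF-11 replicate (adjusted p from 0.00562 to 0.105 over the alternatives). The common subunit gene CGA was at 1.61 ± 0.44 CPM in controls and 1.07 ± 0.03 with GDF-11 (adjusted p = 0.171). Of 17 stromal and fibroblast markers, 5 rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0575, and 0.0349 and 0.0419 without control replicate 1 and without GDF-11 replicate 2, in a range of 0.0349 to 0.173 over the libraries left out). COL1A1 stood at 592 ± 39.0 CPM in controls and rose 1.56-fold, PDGFRB rose 1.62-fold and VIM, which had no whole deposited value, 1.22-fold. In this list 1 gene was lower at an unadjusted p below 0.05 in edgeR and 0 by DESeq2. Of 9 endothelial and blood cell markers, 1 rose (PECAM1, log2 fold change 1.95) and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.749). The mean level of PECAM1 over all libraries was below 1 CPM. CDH5 was at 1.21 and 1.24 CPM and CD68 at 34.9 and 32.1 CPM in controls and with GDF-11.

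Cell cycle lists had few calls. Of 20 S phase genes, 1 rose and 2 fell (camera adjusted p = 0.653), and of 20 G2/M genes, 0 rose and 2 fell (camera adjusted p = 0.191), in both cases over all genes and adjusted over the list alone. CCNE1 rose 1.44-fold, and E2F1, CDT1, HMMR and CDK1 fell 1.20-fold, 1.22-fold, 1.21-fold and 1.13-fold. The G2/M list was called lower without control replicate 3 (camera adjusted p = 0.0023, with a range of 0.0023 to 0.697 over the libraries left out), and the CDK1 call was lost on leaving out any GDF-11 replicate (adjusted p from 0.0581 to 0.0643). Of 19 cholesterol biosynthesis genes, 4 rose and 7 fell, or 4 and 8 adjusted over the list alone (camera adjusted p = 0.0723). The LDL receptor gene LDLR, whose reads were shared with another gene, fell 1.84-fold, MVK and HMGCR fell 1.55-fold and 1.33-fold, and INSIG1, which restrains sterol synthesis, rose 1.62-fold.

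Stress lists showed single members that moved. Of 20 genes of the integrated stress and unfolded protein responses, 3 rose and 4 fell, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.457). The cystine transporter gene SLC7A11 fell 1.84-fold and DDIT3 fell 1.66-fold, while SLC7A5 rose 1.47-fold and ATF4 was at 119 and 121 CPM (adjusted p = 0.723). Of 11 heat shock genes, 2 rose (DNAJB1 and BAG3) and 1 fell (HSPA1B, which has a near-identical copy, HSPA1A, and no whole deposited value), over all genes and adjusted over the list alone (camera adjusted p = 0.402). None of the 13 mitochondrially encoded mRNAs was called over all genes, over the list alone or by DESeq2, with 1 higher and 1 lower at an unadjusted p below 0.05 in edgeR (camera adjusted p = 0.653). Of 14 histone genes kept as a sign of RNA quality, 0 were called over all genes, over the list alone or by DESeq2, and 1 was lower at an unadjusted p below 0.05 in edgeR. Their median log2 fold change was -0.28, and camera called the list lower (adjusted p = 0.0233, and adjusted p = 0.18 with an estimated correlation), a call lost without control replicate 2 (0.0526, in a range of 0.00811 to 0.0526 over the libraries left out). Another division of the libraries gave this list a smaller adjusted p (0.0161).

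By camera, 10 of the 27 lists were higher and 2 lower with GDF-11, and with an estimated correlation 0 were called in either direction (5 higher and 1 lower at an unadjusted p below 0.05). By fry, which does not compare a list with other genes, 15 moved higher and 5 lower on balance and 24 held changes in either direction.

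Among annotation terms, 178 GO and 74 KEGG terms were enriched in the genes that rose. Angiogenesis held 62 such genes among 178 annotated, against 25.4 expected (adjusted p = 9.6e-09, hypergeometric test). Regulation of cell shape held 44 of 108, sequence-specific transcription factor activity 124 of 485, sequence-specific DNA binding 70 of 228, transcription corepressor activity 61 of 191 and negative regulation of transcription 96 of 364. Of the KEGG terms, MicroRNAs in cancer held 54 of 131 (adjusted p = 6.17e-10), Proteoglycans in cancer 57 of 149 (2.18e-09), Pathways in cancer 106 of 362 (2.18e-09) and the TGF-beta signaling pathway 35 of 82 (4.44e-07). Osteoclast differentiation held 29 of 87 (0.000653) and the MAPK signaling pathway 56 of 228 (0.00416). In the genes that fell, 5 GO terms were enriched. They were the cholesterol biosynthetic process (12 of 30, adjusted p = 0.00747), transcriptional activators of RNA polymerase II (43 of 263, 0.0303, with 68 among the genes that rose, 5.61e-05), inhibitors of cyclin-dependent kinases (7 of 13, 0.0312), defense response to virus (24 of 118, 0.0313) and negative regulation of proliferation (40 of 253, 0.0498, with 55 among the genes that rose, 0.0188). The kinase inhibitors were CDKN1B, CDKN1C, CDKN2C, CDKN2D, HEXIM1, HEXIM2 and KAT2B. No KEGG term was enriched in the genes that fell by the hypergeometric test (13 at an unadjusted p below 0.05), and 1 was called with all tested genes as background.

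Control replicate 3 stood apart from the other controls. The chi-square per degree of freedom between counts of controls 1 and 2 was 3.12, against 10.9 and 10.3 for the pairs with control replicate 3 and 1.89 to 2.00 between GDF-11 libraries. Genes in the longest decile by exonic length, compared with those in the shortest decile, were lower in control replicate 3 than in the other controls by a median log2 difference of -0.18. The same measure was 0.15 in control replicate 2 and lay between -0.03 and 0.04 in the remaining libraries. The rank correlation of the deviation with exonic length was -0.32 in control replicate 3 and 0.36 in control replicate 2. Each library was compared with the others of its group, so the values of the controls depend on each other. RN7SL2, a non-coding RNA of the signal recognition particle, was at 154 CPM in control replicate 3 and 10.3 to 12.3 CPM in the other libraries. Control replicate 3 also held 41.3 CPM of CENPE, against 77.2 to 105 CPM elsewhere.

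**Figure D4:**
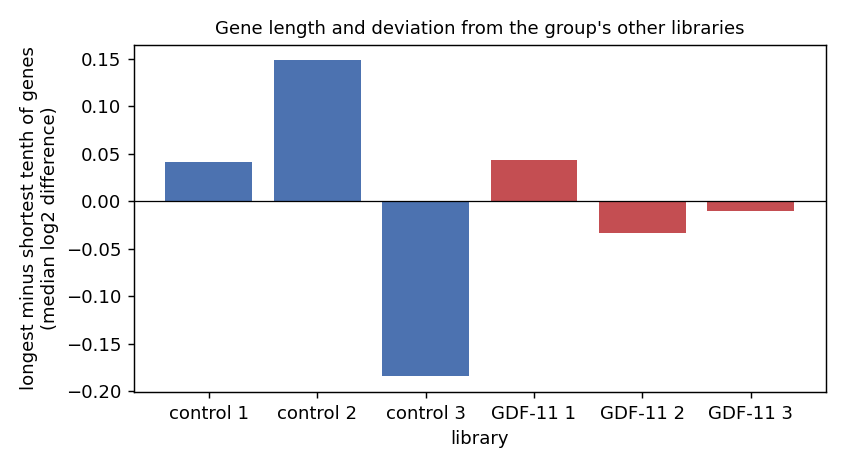
Median log2 difference of each library from the mean of the other libraries of its group, for genes in the longest decile minus genes in the shortest decile by exonic length (bars, controls in blue and GDF-11 in red). Control replicate 3 stands at -0.18, control replicate 2 at 0.15, and the other libraries lie between -0.03 and 0.04.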

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

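The split between directions depended on the setting. Genes lower with GDF-11 numbered 2282 with library totals, 749 by DESeq2, and 785 (without GDF-11 replicate 3) to 1601 (without control replicate 3) on leaving out a library, against 1309 in the main test. Genes higher ranged from 1669 to 2402 on leaving out a library. Without the low-count filter, 214 genes were lower by at least 2-fold. Without control replicate 3, 478 genes were higher and 143 lower at 2-fold or more, and 3242 of the 3471 main calls were kept. With the replicate number as a block, 2068 genes were higher and 1188 lower, but equal numbers did not pair across groups (correlations of -0.062, -0.029 and -0.009). Length offsets gave 2210 higher and 1379 lower. The log2 fold change of ANGPTL4 lay between 4.07 and 4.29. Its adjusted p in edgeR ran from 3.16e-156 without the low-count filter to 2.73e-07 without control replicate 2. The other edgeR settings gave 1.7e-11 (without control replicate 3) or more, and DESeq2 gave 2e-65. Gene lists higher and lower numbered 0 and 0 with an estimated correlation, and lists lower numbered 5 by fry, 1 without control replicate 2 and 3 without control replicate 3. With all tested genes as background, 115 KEGG terms were higher and 1 lower. Without GDF-11 replicate 1, 2 and 3, 69.98%, 70.64% and 70.38% of the main calls were kept. DESeq2 kept 73.87%, leaving out control replicate 2 kept 78.13%, and the other settings kept 85.16% to 99.19%. No call of the main test was made in the opposite direction in any setting. Of 106 called named genes, 104 were called the same way in all settings, the exceptions being CDK1 and SDC1. Named genes were chosen for large changes or small adjusted p, so their stability does not extend to the other calls.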

Other observations

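The genes of this paragraph were chosen after their values were seen. LEFTY2, which encodes an antagonist of the related ligand Nodal and of its receptors, had 0 counts in the controls and 37 in the GDF-11 libraries (11 to 14 each), at least 12.9-fold more with a floor of 3 counts over the group, while the lower 95% counting limit of the ratio is 9.98. VDR, which encodes the vitamin D receptor, rose from 14.6 to 71.2 CPM (log2 fold change 2.29, adjusted p = 2.72e-10 in edgeR's quasi-likelihood test), beside its transcriptional target CYP24A1. PTHLH, which encodes parathyroid hormone-related protein, rose from 1.46 to 12.2 CPM, and UNC5B, a netrin receptor gene, rose from 4.94 to 47.6 CPM. HMOX1, which encodes heme oxygenase, rose from 5.96 to 27.8 CPM. HOXD11 had 1 count against 57, a ratio of 59.6 (95% counting interval 10.3 to 2400).

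These genes were also chosen after their values were seen. CDKN1B, which encodes the cell cycle inhibitor p27, fell from 105.5 to 57.2 CPM (log2 fold change -0.88, adjusted p = 1.94e-07 in edgeR's quasi-likelihood test). CDKN1C fell by the same amount, 0.88 on the log2 scale, and FOXA1, a transcription factor gene, fell from 6.29 to 2.41 CPM. SMAD2/3 signalling slows the cell cycle in many epithelia by inducing cell cycle inhibitor genes such as CDKN2B and CDKN1A. Both are in the SMAD2/3 target list, and in these cells they rose 3.73-fold and 1.38-fold at 3 hours. CDKN1B and CDKN1C, which fell, are not in that list.

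Whether an arbitrary division of the libraries gives such counts was tested with rules written before the result was seen. The real grouping, 1 of 10 splits of the libraries, gave the largest count for genes (3471 against 0) and for lists (12 against at most 10). It also did so for genes at 2-fold (551 against 0) and for terms (257 against 0). Those were counted from called genes, so their 0 followed from the 0 genes called in the other splits. A share of 0.1 is the smallest that 10 splits allow, so the test cannot tell. The other splits gave 166 to 393 genes at an unadjusted p below 0.05 in edgeR against 5306 for the real grouping. They mix the groups 2 to 1. For single genes this puts the treatment difference inside both groups, which widens the spread there and lowers the number of calls. The low gene counts of the other splits are therefore partly fixed by the design. Lists can still carry part of the treatment difference, but that does not account for all the lists the other splits call. G2/M genes were called in 3 of them (smallest camera adjusted p 1.11e-09, against 0.191 for the real grouping), S phase genes (0.0297, against 0.653) and syncytiotrophoblast markers (0.00957, against 0.971) in 1 each, and the histone list, called in the real grouping, had a smaller adjusted p in another split (0.0161, against 0.0233), so differences between libraries unrelated to treatment can give called lists.

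The tests of long transcripts and of non-coding RNA in control replicate 3 were chosen after the result was seen, and the test of depth before. Genes in the longest decile were lower in this library, but a smooth trend with annotated exonic length does not account for its whole distance from the other controls. With that trend removed, the smaller ratio of chi-square values of its pairs over the other control pair was 1.903 (95% interval from resampled genes 1.707 to 2.091). Annotated exonic length is not the length of the transcript expressed, so the test cannot exclude loss of long transcripts as the whole cause. Carry-over of non-coding RNA alone does not account for the distance, since with protein-coding genes the ratio remained 2.356 (2.145 to 2.576). Nor does depth (3.232, 2.26 to 4.615, after thinning to equal totals). The intervals resample genes and not libraries. RNA breakage stays open as a cause, and a difference in that culture, such as its cell cycle state, was not tested.

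The greater number of genes higher than lower at 2-fold or more (429 against 122, a ratio of 3.52) was tested with rules written before the result was seen. Scaling does not account for it (lowest ratio 2.406), nor does a floor at low expression (4.676 among genes of at least 10 CPM in controls), nor control replicate 3 (3.343 without it). A remaining hypothesis is that 3 hours suffice for new transcripts to accumulate but not for stable mRNAs to decay. It could be tested with a time course or with labelling of new RNA.

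All tests of neighbouring genes were chosen after the result was seen. Adjacent here means next in order on a chromosome among 13114 tested protein-coding genes, so untested genes can lie between. Adjacent protein-coding genes were called in the same direction in 635 pairs, against 431.5 ± 17.76 in permutations among genes of like expression and GC content (permutation p = 1e-04, the smallest that 10000 permutations allow). The excess stayed without pairs that overlap or lie within 5 kb (479 against 274.3, permutation p = 1e-04) and without pairs with similar symbols (592 against 411.1, permutation p = 1e-04), so shared reads do not account for it. Examples were DACT1 and DAAM1 (log2 fold changes of 3.99 and 1.76) and FOXA1 and SSTR1 (-1.37 and -1.85), both on chromosome 14. The genes of these pairs lie far apart, with gaps of 540325 and 611940 bp. Copy number differences between cultures and regional features other than GC content were not tested, so the cause stays open.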
